A study of Mus musculus with 16 samples.

How the data were processed

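The deposited values are mean bead intensity per probe and array, not normalized, per the file headers, for 25697 probes on 16 arrays. The deposited detection p-value of each probe on each array, per the file headers, was made against the negative control beads. Both were exported from BeadStudio, per the submitters' processing notes, and its version is not given in the sources used here. The authors also deposited a table of processed intensity, and how it was normalized is not stated per the file headers. Of its values 53.11% sit at 20, the floor, and each of the 16 columns ranks probes most like its own array (Spearman correlation 0.9996 to 1). It was used only as an alternative.

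The 4 groups of 4 arrays follow the labels. Each group has 3 cultures, and culture 3 was measured on 2 arrays. Those 2 arrays were averaged after normalization, so that 12 cultures, 3 per group, entered the main tests. The 2 arrays of culture 3 differed by 0.0973 to 0.106 log2 units, and different cultures of a group by 0.0948 to 0.117. Cultures of a group thus differed little more than 2 arrays of 1 culture. The SE and p-values therefore rest largely on spread between arrays. How independently the cultures were grown cannot be read from these values. Mean intensity parted the arrays into set A (replicate 1 and the first array of replicate 3 of every group, 412 to 454) and set B (replicate 2 and the second array of replicate 3, 369 to 400), so the sets are balanced across groups.

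Intensities were background-corrected with the normal-exponential model using the detection p-values, given an offset of 16, quantile normalized and taken to log2 (neqc in limma 3.58.1, R 4.3.3). A probe was tested if its mean detection p-value was under 0.01 in at least 3 of the 12 cultures. This left 13377 probes, of which 12576 carry a gene symbol (9107 genes) and 801 carry none. Of the 25697 probes, 23978 have 1 symbol, 1719 have none and 0 have several. Gene identifiers of 23962 probes were in the reference gene table and 16 were not, and 0 symbols changed on update. The table gave names and chromosomes, and no positions were used because the array files name no genome build.

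A single linear model of the 4 groups was fitted with limma (8 residual degrees of freedom, 4.37 prior degrees of freedom). The 6 pairwise comparisons and a moderated F-test of any difference among the 4 groups were taken from it. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a probe was called at an adjusted p under 0.05. Errors given with log2 fold changes are moderated standard errors (SE). Fold changes are on background-corrected intensity plus the offset of 16, which understates the fold change of weakly expressed genes. Where no array of a group detected a probe, the fold change is given as at least a bound. The bound sets the mean of the brighter group against, on each array of the other group, the higher of the lowest detected signal on that array and the probe's own signal.

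Genes named from the comparisons with untreated wild-type cells are the 12 called probes with 1 symbol that had the largest increase and the 12 with the largest decrease. Each had all 3 cultures on the same side of the 3 controls. For direct comparisons the number was 6 in each direction. From each gene list up to 4 called members with the largest absolute change and up to 3 of the best-known members that were not called could be named. Genes named by these rules in 1 comparison may also be given in others. Genes picked outside these rules are said to have been chosen after their values were seen.

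The 26 gene lists hold 427 genes: FGF-ERK feedback and targets, FGF ligands and receptors, naive pluripotency, general pluripotency, primed epiblast, primitive endoderm, mesendoderm, neuroectoderm, trophectoderm, heparan sulfate synthesis and core proteins, BMP targets, Wnt targets, LIF-STAT3 pathway, Nodal targets, cholesterol synthesis, oxidative stress, osmotic stress, endoplasmic reticulum (ER) stress and integrated stress response, hypoxia and glycolysis, p53 targets, cell cycle, fibroblast (feeder cells), 2-cell-like state, germline genes silenced by methylation, imprinted genes, and sex chromosome genes. Each gene was represented by its brightest probe. Lists were tested against all other genes with camera (preset correlation between genes 0.01) and Benjamini-Hochberg adjustment over the 26 lists. The same test with a correlation estimated from the data, and fry, were run as alternatives. In fry the directional p-value asks whether the genes of a list move on balance in a single direction, and the mixed p-value whether they change in either direction. Neither compares the list with other genes. Member counts are given over all probes and, where different, with the adjustment made over the list alone.

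The groups, comparisons, filter, model, thresholds, gene lists and the following alternatives were chosen before the data were examined. These were no background correction, an offset of 50, median scaling, cyclic loess, the authors' processed values, no filter, detection in all 12 cultures, the first array of culture 3 alone, all 16 arrays with the culture as a random block, a model of only the 2 groups compared, array weights, the replicate number as a block, an adjusted p under 0.01, a change of at least 2-fold, and leaving out each culture in turn. A block for the slide was not run because the labels name no slides. Alternatives chosen after the data were seen are the array set as a block, each array set alone, and the genes outside chromosomes 8 and 11. List tests with the array set as a block took the 2 arrays of culture 3 as separate replicates. That can make their p-values too small.

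The scripts were first run on simulated values for 13377 probes, with 50 probes changed at each of 4 sizes. They recovered 22% of probes changed by 0.25 log2 units, 56% at 0.5, and 100% at 1 and at 2. Of 148 calls in that comparison 9 were false (6.08%), and the 3 comparisons with no change gave 0 calls. A simulated shift of 0.4 log2 units in the naive pluripotency list was called, with 0 other lists called. Genes were simulated without correlation, so this does not show how the list test behaves where genes of a list vary together. A simulated shared variance of 0.062 between 2 comparisons with the same controls was estimated as 0.0619.

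Shared controls make 2 comparisons correlate without any shared effect. The size of this was taken from 100 simulations with no change in any group, and each pair was also computed with a different untreated culture for each member of the pair.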

Results

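Mouse embryonic stem (ES) cells were profiled to ask how losing the sulfation of heparan sulfate compares with blocking FGF receptors. Wild-type CCE cells were left untreated, or treated for 24 h with 20 mM sodium chlorate, which inhibits sulfation, or with 5 µM SU5402, an FGF receptor inhibitor. The fourth group was untreated Ndst1/2-/- cells, which lack the enzymes that begin the sulfation of heparan sulfate. All cells were grown on gelatin with LIF and serum. Each group had 3 cultures. Arrays detected 12022 to 12821 probes each, and 13377 probes were tested.

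The pluripotency gene Pou5f1 was bright in all 4 groups (mean log2 intensity 12.58 untreated, SD 0.14; 12.49 with chlorate, SD 0.04; 12.43 with SU5402, SD 0.03; 12.66 in Ndst1/2-/- cells, SD 0.16). Over all tested probes, the Ndst1/2-/- cultures lay far from the 9 wild-type cultures on the first principal component (70.8% of variance; 48.9 to 49.3, against -20.6 to -14.1). The second component (14.5%) parted untreated wild-type cultures (-20.7 to -19.3) from those with chlorate (13.7 to 13.9) and SU5402 (7.57 to 8.40). With limma and Benjamini-Hochberg adjustment, 9229 probes (69%) differed among the 4 groups by the F-test.

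**Figure D1:**
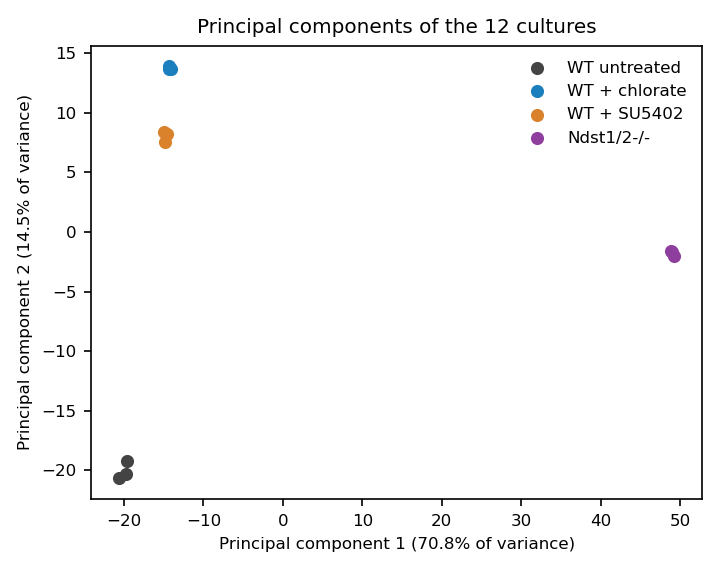
Principal components of 13377 probes. Each point is 1 of 12 cultures, coloured by group, and the axes give the score on components 1 and 2 with the percentage of variance.

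Chlorate lowered feedback genes of FGF-ERK signalling. Etv4, an ETS factor induced by ERK, fell 11.1-fold (log2 fold change -3.47 ± 0.08 SE, n = 3 cultures per group; limma with Benjamini-Hochberg, adjusted p = 1.39e-10). The ERK phosphatase gene Dusp6 fell 4.38-fold (-2.13 ± 0.08), with Dusp4 (-2.14 ± 0.08) and the Sprouty inhibitor Spry4 (-2.00 ± 0.13). The homeobox gene Gbx2 (-2.60 ± 0.07) and Pou3f1, a POU factor of the primed epiblast (-1.91 ± 0.08), also fell. Gata2, a zinc-finger factor of blood and trophoblast, rose 7.35-fold (2.88 ± 0.08; limma with Benjamini-Hochberg, adjusted p = 1.73e-10).

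Among other genes that rose were Spic, an ETS factor of macrophages (2.61 ± 0.10), the membrane protein gene Lrrc15 (2.22 ± 0.08), the pepsinogen gene Pga5 (2.19 ± 0.08) and the actin-associated gene Pdlim4 (2.10 ± 0.08). The organizer gene Gsc (1.76 ± 0.06), Sox21 (1.72 ± 0.06), the epithelial ETS factor gene Elf3 (1.70 ± 0.08), the protease gene Klk7 (1.90 ± 0.09, detected on 1 of 4 untreated arrays), Ifitm1 (1.88 ± 0.11), Cyp1b1 (1.76 ± 0.11) and the water channel gene Aqp3 (1.69 ± 0.08) rose too. Decreases included the amino acid transporter gene Slc7a7 (-2.37 ± 0.10), the endothelial genes Robo4 (-2.22 ± 0.10) and Esam (-2.19 ± 0.11), Pdk1, a kinase that restrains pyruvate oxidation (-2.21 ± 0.07), and Wt1 (-1.94 ± 0.10). Nt5e, an ecto-nucleotidase gene, was detected on 0 of 4 chlorate arrays and was at least 4.14-fold lower. In all, 1904 probes were higher and 1899 lower with chlorate (28.4% of probes; 1489 and 1487 genes), of which 94 and 77 changed at least 2-fold. With median scaling in place of quantile normalization 37.7% of the calls were higher, against 50.1%.

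Of 18 tested FGF-ERK feedback and target genes 12 fell with chlorate and 3 rose (median log2 fold change -0.50). The list shifted down against other genes (camera in limma with Benjamini-Hochberg, adjusted p = 4.09e-06; adjusted p = 0.0554 with an estimated correlation). The growth regulator Myc fell (-1.43 ± 0.09, detected on 2 of 4 chlorate arrays), whereas the immediate early gene Egr1 (-0.13 ± 0.06) and Spry2 (-0.43 ± 0.20, detected on 1 of 4 chlorate arrays) did not pass. Of 15 naive pluripotency genes 12 rose and 2 fell (median 0.53, or 0.47 with undetected genes at their bound). The homeobox gene Nanog (0.92 ± 0.06), Dppa3, a maternal factor of the naive state (1.21 ± 0.06), and Tbx3 (0.99 ± 0.09) rose, Gbx2 fell, and Dppa5a (0.08 ± 0.06) did not pass. That list was called up (camera in limma with Benjamini-Hochberg, adjusted p = 1.32e-05; adjusted p = 0.0512 with an estimated correlation).

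Of 13 primed epiblast genes 9 fell with chlorate and 2 rose (median -0.50, or -0.35 with undetected genes at their bound). Beside Pou3f1, the Wnt ligand gene Wnt8a fell (-0.96 ± 0.10), and Zic2 (-0.17 ± 0.12) did not pass (limma camera with Benjamini-Hochberg, adjusted p = 0.00200; adjusted p = 0.0760 with an estimated correlation). Trophectoderm genes moved up, with 6 of 10 higher and 0 lower (7 and 1 adjusted over the list alone; median 0.36). Gata3 (1.53 ± 0.07), Tfap2c, an AP-2 factor (1.505 ± 0.055), and the X-linked homeobox gene Rhox9 (1.13 ± 0.08) rose, while the lineage factor gene Cdx2 (0.08 ± 0.07) did not pass. The trophectoderm adjusted p was 0.000282 with limma camera and Benjamini-Hochberg (adjusted p = 0.0760 with an estimated correlation).

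Of 9 BMP targets 6 rose and 1 fell with chlorate (median 0.40): Id4 (1.39 ± 0.12), Id2 (1.04 ± 0.09) and the homeobox gene Msx1 (0.91 ± 0.08) rose, and the ligand gene Bmp4 fell (-1.63 ± 0.07). The list was called up (limma camera with Benjamini-Hochberg, adjusted p = 0.0219; adjusted p = 0.243 with an estimated correlation, and 0.0665 in array set A alone). Of 18 genes of ER stress and the integrated stress response 8 fell and 0 rose (median -0.19), among them Chac1, which degrades glutathione (-0.66 ± 0.07), and the mitochondrial folate enzyme gene Mthfd2 (-0.51 ± 0.10). Atf4, the central factor of that response, did not pass (-0.13 ± 0.12). The list was called down (limma camera with Benjamini-Hochberg, adjusted p = 0.00669; adjusted p = 0.0760 with an estimated correlation). None of the 6 lists called for chlorate was kept with an estimated correlation.

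The other 20 lists were not called for chlorate (limma camera with Benjamini-Hochberg, adjusted p from 0.0711 to 0.855). Of 15 primitive endoderm genes 8 rose and 1 fell (8 and 2 over the list alone), including the laminin gene Lama1 (0.69 ± 0.07), while Gata4, detected on 1 of 4 untreated and 0 of 4 chlorate arrays, did not pass. Of 5 mesendoderm genes 2 rose (3 higher and 1 lower over the list alone), Gsc and Fgf8 (1.33 ± 0.09), and Eomes (-0.19 ± 0.07) did not pass. Both lists had an adjusted p of 0.0711 (limma camera with Benjamini-Hochberg) and passed at 0.0496 without untreated replicate 3.

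Of 10 FGF ligand and receptor genes 5 rose and 2 fell with chlorate, among them Fgf10 (0.81 ± 0.07), Fgfr2, at least 1.41-fold higher, and Fgf15 (-0.73 ± 0.10). Of 26 genes of heparan sulfate synthesis and core proteins 8 rose and 4 fell (9 and 4 over the list alone): the sulfotransferase gene Hs6st1 rose (1.19 ± 0.07), the polymerase gene Ext1 fell (-0.49 ± 0.07), and Hs2st1 (-0.11 ± 0.06) did not pass. General pluripotency genes were split, with 3 of 10 higher and 5 lower, including Utf1 (-1.504 ± 0.07) and Dppa4 (-0.59 ± 0.06), while Pou5f1 (-0.10 ± 0.09) did not pass. Of 13 imprinted genes 3 rose and 4 fell (4 and 4 over the list alone), with the growth factor gene Igf2 (1.16 ± 0.07) and Peg3 (0.86 ± 0.10) higher and Grb10 (-0.47 ± 0.08) lower. Of 5 2-cell-like genes 2 rose, among them the deubiquitinase gene Usp17la (0.53 ± 0.08), and of 7 germline genes 1 rose and 4 fell, among them Taf7l (-0.85 ± 0.12).

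Other signalling lists moved both ways with chlorate: 1 higher and 2 lower of 7 Wnt targets (Axin2 0.03 ± 0.15, not called), 2 and 3 of 11 LIF-STAT3 genes (3 and 3 over the list alone; Socs3 -0.13 ± 0.06, not called), and 3 and 2 of 6 Nodal targets (Lefty1 0.52 ± 0.06). Metabolic and stress lists held 3 higher and 0 lower of 17 cholesterol genes (Ebp 0.52 ± 0.06), 3 and 5 of 13 oxidative stress genes (the metallothionein gene Mt1 -1.01 ± 0.06), 1 and 0 of 4 osmotic stress genes (Slc6a6 0.72 ± 0.06), and 3 and 2 of 13 hypoxia and glycolysis genes (Vegfa 0.98 ± 0.06). The cholesterol calls of Hsd17b7 and Fdps were lost without untreated replicate 2 (limma with Benjamini-Hochberg, adjusted p = 0.0628 and 0.09) and without some other single cultures. Calls of Sp5, the Wnt target that rose, and of Lifr, Tdgf1, Twist1, Aurka, E2f1 and Ccne2 were each lost without at least 1 single culture. Of 15 p53 targets Cdkn1a rose (0.54 ± 0.08) and Pmaip1 fell (-0.97 ± 0.07), and Mdm2 (-0.03 ± 0.06) did not pass. Of 20 cell cycle genes 3 rose and 2 fell, among them Ccne1 (-0.42 ± 0.08). Of 5 neuroectoderm genes 1 fell (Neurod1 -0.45 ± 0.10), of 7 fibroblast genes 2 fell (Thy1 -0.60 ± 0.09), and of 3 sex chromosome genes none passed (Kdm5d 0.08 ± 0.05).

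SU5402 lowered many of the same genes. Gbx2 fell 5.74-fold (log2 fold change -2.52 ± 0.07 SE, n = 3 cultures per group; limma with Benjamini-Hochberg, adjusted p = 6.39e-10), and Etv4 4.93-fold (-2.30 ± 0.08; limma with Benjamini-Hochberg, adjusted p = 3.01e-09). Pou3f1 (-1.80 ± 0.08), Spry4 (-1.59 ± 0.13), Dusp6 (-1.33 ± 0.08) and Bmp4 (-1.59 ± 0.07) also fell. Gata2 rose 6.07-fold (2.60 ± 0.08; limma with Benjamini-Hochberg, adjusted p = 1.19e-09).

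Lrrc15 (2.19 ± 0.08), Spic (2.05 ± 0.10), Pdlim4 (1.90 ± 0.08), Pga5 (1.67 ± 0.08) and Cyp1b1 (1.62 ± 0.11) were next among increases with SU5402. They were followed by Sox21 (1.59 ± 0.06), Klk7 (1.57 ± 0.09), Tfap2c (1.56 ± 0.06), the lipid synthesis gene Gpat3 (1.52 ± 0.10), Elf3 (1.41 ± 0.08) and Rhox9 (1.39 ± 0.08). Wt1 (-2.11 ± 0.10), Slc7a7 (-2.05 ± 0.10), Esam (-1.86 ± 0.11), Robo4 (-1.78 ± 0.10), the helix-loop-helix gene Tcf15 (-1.68 ± 0.07) and Ccdc3 (-1.62 ± 0.09) fell. The endothelin gene Edn2 was at least 2.88-fold lower. In all, 1597 probes were higher and 1548 lower (23.5%; 1261 and 1233 genes), and 60 and 49 changed at least 2-fold.

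Of 15 naive pluripotency genes 12 rose with SU5402 and 2 fell (median 0.45), with Dppa3 (1.12 ± 0.06), Tbx3 (0.81 ± 0.09) and Nanog (0.78 ± 0.06) higher and Dppa5a (0.07 ± 0.06) not called. The list was called up (limma camera with Benjamini-Hochberg, adjusted p = 2.08e-05). Of 13 primed epiblast genes 9 fell and 2 rose (median -0.67, or -0.40 with undetected genes at their bound). Among them were Wnt8a (-1.05 ± 0.10) and the DNA methyltransferase gene Dnmt3b (-0.77 ± 0.06), and Zic2 (-0.05 ± 0.12) did not pass (limma camera with Benjamini-Hochberg, adjusted p = 0.000110). Of 10 trophectoderm genes 7 rose and 0 fell (8 and 0 over the list alone; median 0.46), including Gata3 (1.31 ± 0.07) and Rhox6 (1.05 ± 0.09) but not Cdx2 (0.07 ± 0.07; limma camera with Benjamini-Hochberg, adjusted p = 1.27e-06). These 3 lists were kept with an estimated correlation (adjusted p = 0.0317 each).

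Of 18 FGF-ERK genes 9 fell with SU5402 and 1 rose (11 and 1 over the list alone; median -0.29), among them Myc (-1.43 ± 0.09, detected on 2 of 4 SU5402 arrays), with Spry2 (0.05 ± 0.20) not called. The list was called down (limma camera with Benjamini-Hochberg, adjusted p = 0.000101; adjusted p = 0.0709 with an estimated correlation). Of 5 mesendoderm genes 3 rose (median 0.31), namely Gsc (1.38 ± 0.06), Fgf8 (1.02 ± 0.09) and Evx1 (0.31 ± 0.07), and Eomes (0.03 ± 0.07) did not pass (limma camera with Benjamini-Hochberg, adjusted p = 0.0221; adjusted p = 0.0921 with an estimated correlation, and 0.0641 in array set B alone). Of 18 ER stress genes 6 fell and 0 rose (7 and 0 over the list alone; median -0.13), including Mthfd2 (-0.44 ± 0.10) and the serine synthesis gene Phgdh (-0.39 ± 0.07), with Atf4 (-0.13 ± 0.12) not called (limma camera with Benjamini-Hochberg, adjusted p = 0.0178; adjusted p = 0.0921 with an estimated correlation, and 0.148 in array set B alone).

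Of 15 primitive endoderm genes 8 rose with SU5402 and 1 fell (8 and 3 over the list alone; median 0.29), among them the basement membrane genes Col4a2 (0.55 ± 0.12) and Col4a1 (0.52 ± 0.06). Of 20 cell cycle genes 6 rose and 1 fell (median 0.12), among them the mitotic kinase gene Aurka (0.35 ± 0.06) and the nucleotide reductase gene Rrm2 (0.33 ± 0.06). Both lists were called up at an adjusted p of 0.0456 (limma camera with Benjamini-Hochberg; adjusted p = 0.0964 with an estimated correlation). Each call depended on single cultures: without SU5402 replicate 3 the adjusted p was 0.0864 for primitive endoderm and 0.0678 for cell cycle, and without untreated replicate 1 it was 0.0769 for cell cycle (limma camera with Benjamini-Hochberg). The calls were also lost without untreated replicate 2 (0.0565 and 0.0670), chlorate replicate 2 (0.0523 and 0.0515), Ndst1/2-/- replicate 1 (0.0540 both) and replicate 3 (0.0525 both), primitive endoderm without chlorate replicate 1 (0.0555) and with the authors' values (0.114), and cell cycle without SU5402 replicate 1 (0.0516) or 2 (0.0638) and with the mean of all detected probes (0.0825).

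The other 18 lists were not called for SU5402 (limma camera with Benjamini-Hochberg, adjusted p from 0.0673 to 0.949). Of 26 heparan sulfate genes 10 rose and 4 fell (12 and 4 over the list alone), with Hs6st1 (1.05 ± 0.07) and the core protein gene Hspg2 (0.50 ± 0.07) higher and the sulfatase gene Sulf1 (-0.38 ± 0.05) lower. That list passed without SU5402 replicate 1 (adjusted p = 0.0421 against 0.0673, limma camera with Benjamini-Hochberg). It also passed with the array set as a block (0.0455), where the 2 arrays of culture 3 counted as separate replicates. FGF ligands and receptors had 4 of 10 higher and 2 lower (6 and 2 over the list alone; Fgf5 at least 1.20-fold lower). General pluripotency had 2 of 10 higher and 4 lower (3 and 4 over the list alone), with Sox2 (0.38 ± 0.09) higher, Utf1 (-1.10 ± 0.07) lower and Pou5f1 (-0.15 ± 0.09) not called. BMP targets had 4 of 9 higher and 1 lower (5 and 1 over the list alone; Id4 1.06 ± 0.12), Wnt targets 0 and 2 of 7 (1 and 2 over the list alone; Ccnd1 -0.30 ± 0.07), LIF-STAT3 genes 1 and 2 of 11 (Socs3 -0.38 ± 0.06), and Nodal targets 2 and 2 of 6 (Lefty1 0.61 ± 0.06, Lefty2 0.54 ± 0.07).

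Of 13 hypoxia and glycolysis genes 2 rose and 4 fell with SU5402, with Vegfa (0.68 ± 0.06) higher and Pdk1 (-1.58 ± 0.07) lower. Oxidative stress genes had 4 of 13 higher and 4 lower (4 and 5 over the list alone; Gstm1 0.77 ± 0.07, Mt1 -0.67 ± 0.06), cholesterol genes 1 and 1 of 17 (Ebp 0.50 ± 0.06), osmotic stress genes 1 and 1 of 4 (Slc6a6 0.51 ± 0.06), and p53 targets 1 and 2 of 15 (Cdkn1a 0.52 ± 0.08, Pmaip1 -0.69 ± 0.07). Imprinted genes had 3 of 13 higher and 5 lower (Igf2 0.83 ± 0.07, Snrpn -0.43 ± 0.07), germline genes 1 and 2 of 7 (2 and 2 over the list alone; Sycp1 -0.02 ± 0.08, not called), and 2-cell-like genes 0 and 2 of 5 (0 and 3 over the list alone; Tcstv3 -0.35 ± 0.06). Neuroectoderm genes had 2 of 5 higher and 2 lower (Neurod1 -0.50 ± 0.10), fibroblast genes 1 and 1 of 7 (Thy1 -0.74 ± 0.09), and sex chromosome genes 1 and 0 of 3 (Kdm5d -0.07 ± 0.05, not called). The higher neuroectoderm calls, Map2 and Nes, were lost without untreated replicate 1 (limma with Benjamini-Hochberg, adjusted p = 0.16 and 0.106). The germline calls (Stra8, Taf7l and Ddx4) and the lower Nodal target calls (Tdgf1 and Skil) were each lost without at least 1 single culture. The same held for the sex chromosome call (Eif2s3y), Dll1, Tagln, Bbc3 and Zscan4c.

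In Ndst1/2-/- cells the FGF-ERK genes Etv4 (log2 fold change -2.67 ± 0.08 SE, n = 3 cultures per group), Dusp4 (-2.22 ± 0.08) and Spry4 (-1.97 ± 0.13) fell against untreated wild-type cells, as did Pou3f1 (-2.55 ± 0.08). Larger changes were in other genes. The solute transporter gene Slc51a rose 15.3-fold (3.94 ± 0.08; limma with Benjamini-Hochberg, adjusted p = 1.82e-12), and the mitotic kinase gene Plk1, on its 1 probe, 14.7-fold (3.88 ± 0.11). The skeletal actin gene Acta1 was at least 9.64-fold lower and detected on 0 of 4 Ndst1/2-/- arrays, and the keratin gene Krt8 fell (-3.27 ± 0.07). No probe in the platform table is named Ndst1 or Ndst2, so the deleted genes were not analysed here.

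Further increases in Ndst1/2-/- cells were in Nod1, a sensor of bacterial cell wall (3.85 ± 0.08), the LIM protein gene Csrp1 (3.56 ± 0.13), the oligodendrocyte factor gene Olig1 (3.55 ± 0.12), and Pygb, a glycogen phosphorylase (3.17 ± 0.09). The Wnt antagonist gene Sfrp1 (3.14 ± 0.09), the chemokine gene Ccl25 (3.13 ± 0.10) and the helix-loop-helix gene Msc (3.06 ± 0.06) rose too. The chondroitin sulfotransferase gene Chst3 was at least 6.48-fold higher, Ccl27a at least 5.89-fold and Gm13043 at least 5.62-fold, as none of these was detected in untreated wild-type cells. The germline and ferritin-like genes Fthl17f (-3.72 ± 0.08), Nlrp4c (-3.54 ± 0.08) and Nlrp14 (-3.47 ± 0.12) fell, with Wt1 (-3.61 ± 0.10), the epithelial splicing gene Esrp1 (-3.46 ± 0.08) and Plac8 (-3.37 ± 0.06). Wt1 and Nlrp4c were detected on 1 of 4 Ndst1/2-/- arrays each, so the size of their decrease rests on signal near background. The iron exporter gene Slc40a1 was at least 8.12-fold lower, Gbp2b at least 7.17-fold, Epha1 at least 6.61-fold and Gbp2 at least 6.44-fold. In all, 4069 probes were higher and 4312 lower (62.7%; 2945 and 3192 genes), and 568 and 637 changed at least 2-fold.

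Of 13 imprinted genes 12 fell in Ndst1/2-/- cells and 1 rose (median -1.29). The placental growth regulator Phlda2 (-3.15 ± 0.06), the cell cycle inhibitor Cdkn1c (-2.39 ± 0.06) and Igf2 (-2.26 ± 0.07) fell, and the Notch ligand homologue Dlk1 was at least 2.47-fold lower. The list was called down (limma camera with Benjamini-Hochberg, adjusted p = 1.52e-05). With an estimated correlation this list alone was kept in this comparison (adjusted p = 0.0378).

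Of 18 FGF-ERK genes 10 fell in Ndst1/2-/- cells and 2 rose (11 and 2 over the list alone; median -0.71), including Fgfbp1, which releases FGFs from matrix (-1.59 ± 0.08). Spry2 (-0.03 ± 0.20) did not pass. Of 15 naive genes 11 rose and 2 fell (12 and 2 over the list alone; median 0.68), with Tbx3 higher (1.43 ± 0.09), Prdm14 at least 2.10-fold higher, Dppa3 (-2.71 ± 0.06) and Gbx2 (-1.40 ± 0.07) lower, and Zfp42 (0.16 ± 0.07) not called. Both lists were called (limma camera with Benjamini-Hochberg, adjusted p = 0.00548 each; adjusted p = 0.127 and 0.0652 with an estimated correlation).

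Of 6 Nodal targets 5 fell in Ndst1/2-/- cells and 0 rose (median -1.19), including the Nodal inhibitors Lefty2 (-2.04 ± 0.07) and Lefty1 (-1.23 ± 0.06), while Nodal itself (-0.11 ± 0.08) did not pass. Of 15 p53 targets 10 fell and 1 rose (median -0.44, or -0.42 with undetected genes at their bound), with Pmaip1 (-1.81 ± 0.07) and Cdkn1a (-1.06 ± 0.08) lower. Of 20 cell cycle genes 12 rose and 1 fell (median 0.37), with Plk1 and Rrm2 (1.21 ± 0.06) higher, Ccne1 (-0.62 ± 0.08) lower and Top2a (-0.13 ± 0.07) not called. Of 18 ER stress genes 10 rose and 0 fell (median 0.27), with Atf4 (1.39 ± 0.12) and the folate enzyme gene Shmt2 (1.37 ± 0.06) higher and Ddit3 (0.18 ± 0.08) not called. Each of these 4 lists was called (limma camera with Benjamini-Hochberg, adjusted p = 0.00548; adjusted p = 0.0652 with an estimated correlation).

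Of 7 germline genes 5 fell in Ndst1/2-/- cells and 0 rose (6 and 0 over the list alone; median -1.20, or -1.13 with undetected genes at their bound), among them Asz1 (-2.01 ± 0.11) and Taf7l (-1.75 ± 0.12; limma camera with Benjamini-Hochberg, adjusted p = 0.0147; adjusted p = 0.0844 with an estimated correlation). All 4 tested osmotic stress genes rose (median 0.61), including Slc6a6 (0.84 ± 0.06) and the osmotic factor gene Nfat5 (0.70 ± 0.06; limma camera with Benjamini-Hochberg, adjusted p = 0.0412; adjusted p = 0.122 with an estimated correlation, and 0.0953 without genes of chromosomes 8 and 11). Of 13 primed epiblast genes 8 fell and 2 rose (median -0.68, or -0.26 with undetected genes at their bound), among them the tight junction gene Cldn6 (-2.54 ± 0.06) and Dnmt3b (-2.01 ± 0.06), with Sox4 (0.22 ± 0.16) not called. The primed call (limma camera with Benjamini-Hochberg, adjusted p = 0.0485; adjusted p = 0.136 with an estimated correlation) was lost with the authors' values (0.0796). It was also lost without chlorate replicate 1 (0.0574) or 2 (0.0576), Ndst1/2-/- replicate 2 (0.0509), or SU5402 replicate 1 (0.0558), 2 (0.0541) or 3 (0.0535).

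The other 16 lists were not called for Ndst1/2-/- cells (limma camera with Benjamini-Hochberg, adjusted p from 0.0664 to 0.978). Of 10 trophectoderm genes 6 fell and 2 rose: Krt8 fell, Krt18 was at least 7.33-fold and Cdx2 at least 1.68-fold lower, and Rhox6 fell (-1.03 ± 0.09, detected on 1 of 4 Ndst1/2-/- arrays). This list passed without Ndst1/2-/- replicate 1 (adjusted p = 0.0359 against 0.0664, limma camera with Benjamini-Hochberg) and in array set B alone (0.0334). Of 26 heparan sulfate genes 14 rose and 4 fell (median 0.29), with Hs6st1 (1.43 ± 0.07) and the core protein genes Hspg2 (1.31 ± 0.07) and Agrn (0.94 ± 0.06) higher and Hs3st1 at least 1.39-fold lower, and this list passed in array set A alone (limma camera with Benjamini-Hochberg, adjusted p = 0.0469 against 0.0669). Of 7 Wnt targets 2 rose and 4 fell (median -1.06, or -0.26 with undetected genes at their bound): Notum rose (1.36 ± 0.07), Axin2 fell (-1.66 ± 0.15) and Sp5 was at least 5.42-fold lower. Of 9 BMP targets 3 rose and 6 fell, including Smad6 (1.08 ± 0.09), Bmp4 (-1.51 ± 0.07) and Id1 (-1.21 ± 0.08). Of 11 LIF-STAT3 genes 7 rose and 2 fell, including Bcl3 (1.11 ± 0.10) and Cish (0.997 ± 0.07).

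FGF ligands and receptors had 4 of 10 genes higher and 4 lower in Ndst1/2-/- cells (Fgf17 1.77 ± 0.06, Fgf4 0.997 ± 0.09, Fgf8 at least 1.51-fold lower). General pluripotency genes had 4 and 4 of 10 (Utf1 -0.94 ± 0.07; Pou5f1 0.08 ± 0.09, not called), and primitive endoderm genes 6 and 6 of 15 (Lamc1 1.52 ± 0.07, Amn -1.70 ± 0.13 and detected on 2 of 4 arrays, Gata6 at least 1.78-fold lower). Mesendoderm genes had 1 and 1 of 5 (Gsc 1.35 ± 0.06), neuroectoderm genes 0 and 4 of 5 (Map2 -1.24 ± 0.15), and fibroblast genes 1 and 5 of 7 (Acta2 -1.76 ± 0.08, Thy1 at least 2.62-fold lower). Of 17 cholesterol genes 5 rose and 3 fell (Stard4 -1.34 ± 0.07), of 13 oxidative stress genes 5 and 5 (Nqo1 1.87 ± 0.07, Mt1 -1.20 ± 0.06), and of 13 hypoxia genes 6 and 7 (Vegfa 1.67 ± 0.06, Ldha -1.59 ± 0.06). Of 5 2-cell-like genes 2 rose and 2 fell (Tcstv1 0.94 ± 0.08, Usp17la -0.51 ± 0.08). Of 3 sex chromosome genes 2 fell, Eif2s3y (-0.31 ± 0.06) and Kdm5d, at least 1.79-fold lower.

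In Ndst1/2-/- cells genes of chromosome 8 were shifted up (median log2 fold change 0.32, 76.5% of 489 genes positive, 301 called higher and 65 lower) and genes of chromosome 11 down (-0.33, 26.2% of 803 positive, 113 higher and 479 lower). The other 18 chromosomes had medians from -0.14 (X, 36.3% of 325 genes positive, 58 higher and 149 lower) to 0.13 (chromosome 14, 61.5% of 322, 136 higher and 80 lower). With chlorate all 20 medians lay between -0.04 and 0.00819, and with SU5402 between -0.02 and 0.02. This grouping by chromosome was chosen after the values were seen.

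**Figure D2:**
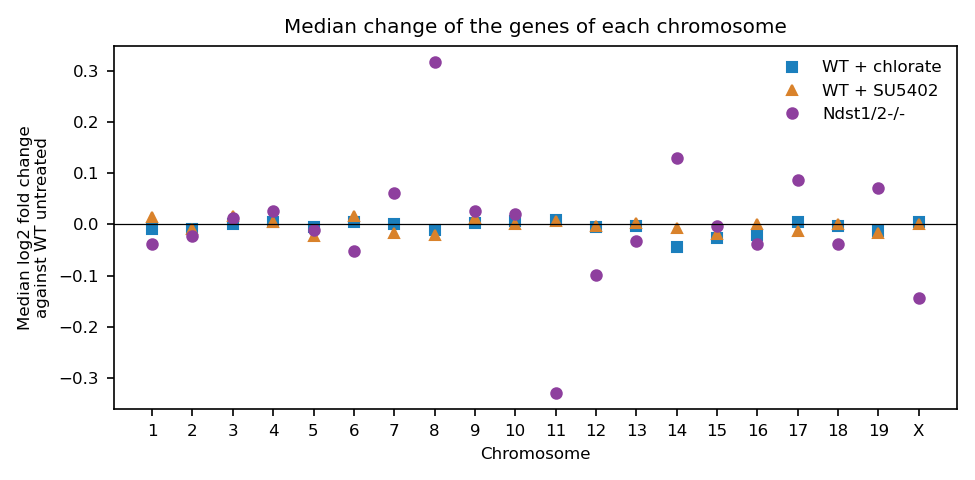
Median log2 fold change of the genes of each chromosome against untreated wild-type cells, for chlorate, SU5402 and Ndst1/2-/- cells. The axes give the chromosome and the median log2 fold change.

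**Figure D3:**
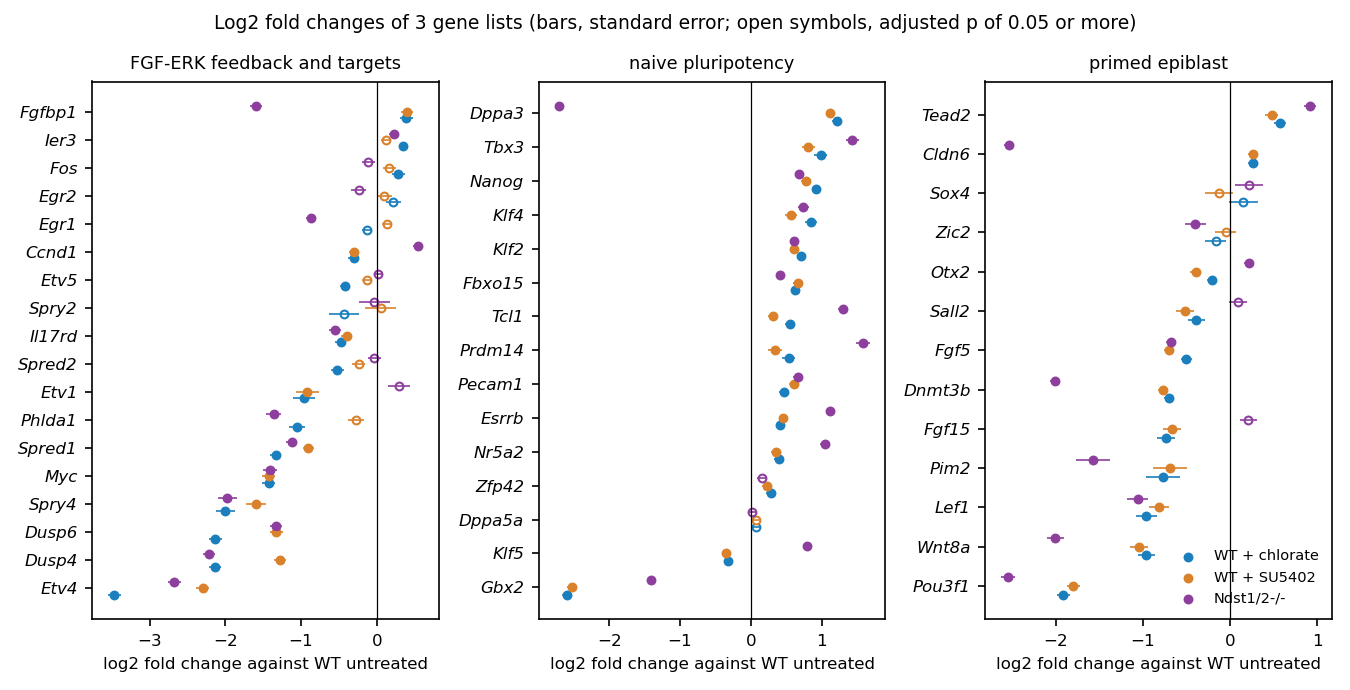
Log2 fold change of genes of the FGF-ERK, naive pluripotency and primed epiblast lists against untreated wild-type cells, for chlorate, SU5402 and Ndst1/2-/- cells. Bars are the SE with 3 cultures per group, and open symbols have an adjusted p of 0.05 or more.

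For some lists the median, the mean and the test differ in sign. With chlorate these are Wnt targets (median 0.01, mean -0.14, test down), LIF-STAT3 (0.03, -0.17, down), hypoxia and glycolysis (0.06, -0.02, up) and p53 targets (0.00336, -0.02, down). With SU5402 they are Nodal targets (-0.02, 0.06, up), cholesterol (-0.03, -0.00490, up), osmotic stress (-0.02, 0.03, up) and fibroblast genes (0.04, -0.04, down). In Ndst1/2-/- cells they are general pluripotency (0.13, -0.13, down), oxidative stress (-0.00872, 0.10, up) and 2-cell-like genes (-0.07, 0.05, up). In Ndst1/2-/- cells the FGF ligand and receptor median was 0.07, or -0.03 with undetected genes at their bound. By fry with Benjamini-Hochberg, 24 of 26 lists had members that changed in either direction with chlorate, 25 with SU5402 and 26 in Ndst1/2-/- cells.

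The direct comparison of the 2 inhibitors gave few calls. Of 13377 probes 2202 had an unadjusted p under 0.05 (limma), so more probes may differ than were called. Etv4 was higher with SU5402 than with chlorate (log2 difference 1.17 ± 0.08 SE, n = 3 cultures per group; limma with Benjamini-Hochberg, adjusted p = 2.46e-05), as were Dusp4 (0.86 ± 0.08), Dusp6 (0.80 ± 0.08) and Phlda1, an ERK-induced gene (0.78 ± 0.10). Nt5e was at least 1.93-fold and the lymphotoxin gene Ltb at least 1.61-fold higher with SU5402. Gm428 (-1.15), Msx1 (-0.71 ± 0.08) and the Prame-like genes Pramel39 (-0.88), Pramel37 (-0.70) and Pramel20 (-0.69) were lower with SU5402, as was Rgcc (-0.68), whose call was lost without chlorate replicate 2 (limma with Benjamini-Hochberg, adjusted p = 0.0515). In all, 139 probes were higher and 201 lower (2.54%; 126 and 172 genes), and 2 and 3 of these differed at least 2-fold. These counts depend on single cultures: 64 were higher without SU5402 replicate 2, and 88 lower without chlorate replicate 1. Of the calls 40.9% were higher, against 48.7% with median scaling, and array sets A and B alone gave too few calls for a share (5 higher and 16 lower, and 3 and 3).

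FGF-ERK genes were higher with SU5402 than with chlorate, 7 of 18 and 0 lower (9 and 1 over the list alone; median 0.28; limma camera with Benjamini-Hochberg, adjusted p = 2.59e-06; adjusted p = 0.0581 with an estimated correlation). Of 5 2-cell-like genes 3 were lower and 0 higher (4 and 0 over the list alone; median -0.44): Zscan4c (-0.64 ± 0.08), Usp17la (-0.60 ± 0.08) and Tcstv3 (-0.44 ± 0.06). That list had an adjusted p of 2.59e-06 (limma camera with Benjamini-Hochberg) and was the only list of this comparison kept with an estimated correlation (adjusted p = 0.04996). Of 9 BMP targets 3 were lower (5 over the list alone; median -0.33; limma camera with Benjamini-Hochberg, adjusted p = 0.000138; adjusted p = 0.0880 with an estimated correlation). The calls of Id2 and Id1 were lost without SU5402 replicate 2 (limma with Benjamini-Hochberg, adjusted p = 0.135 and 0.101) and without several other single cultures. Of 13 oxidative stress genes 4 were higher (median 0.15), among them Hmox1 (0.51 ± 0.06) and Mt1 (0.33 ± 0.06; limma camera with Benjamini-Hochberg, adjusted p = 0.00147; adjusted p = 0.114 with an estimated correlation). The other calls, Mt2 and Srxn1, were lost without chlorate replicate 1 (limma with Benjamini-Hochberg, adjusted p = 0.112 and 0.0737) and without some other single cultures. Cell cycle genes were higher on balance (median 0.10; limma camera with Benjamini-Hochberg, adjusted p = 0.0174; adjusted p = 0.0880 with an estimated correlation, and 0.0847 in array set A alone), with none of 20 called singly.

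FGF ligands and receptors (median -0.10, 1 of 10 lower, 3 over the list alone), trophectoderm (0.12, 0 of 10 called, 4 higher and 1 lower over the list alone) and germline genes (0.22, 1 of 7 higher, 3 over the list alone) were called at an adjusted p of 0.0468 (limma camera with Benjamini-Hochberg; adjusted p = 0.184, 0.233 and 0.163 with an estimated correlation). All 3 calls were lost without untreated replicate 2 (0.0535 each) and without SU5402 replicate 3 (0.0701, 0.0701 and 0.160). Single lists also lost their call without chlorate replicate 1 (FGF ligands 0.0677, trophectoderm 0.163), chlorate replicate 2 (FGF ligands 0.0960, germline 0.1), SU5402 replicate 2 (FGF ligands 0.123, trophectoderm 0.0861) or untreated replicate 3 (trophectoderm 0.0547), and with the authors' values (FGF ligands 0.118) or the mean of all detected probes (trophectoderm 0.0936). Hypoxia and glycolysis (limma camera with Benjamini-Hochberg, adjusted p = 0.0568) was not called but passed without untreated replicate 1 (0.0493), without chlorate replicate 3 (0.0472) and with the authors' values (0.0331), and cholesterol synthesis (0.107) passed without SU5402 replicate 2 (0.0370).

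Ndst1/2-/- cells also differed from inhibitor-treated wild-type cells in many genes. Against chlorate, Plk1 (3.87 ± 0.11), Nod1 (3.77 ± 0.08), Csrp1 (3.24), Olig1 (3.21) and Hebp1, a haem-binding protein gene (3.10), were higher and Ccl27a at least 6.02-fold higher. Dppa3 (-3.92 ± 0.06), Fthl17f (-3.57) and Krt8 (-3.56 ± 0.07) were lower, with Acta1 at least 15.0-fold, Rasgrp1 at least 10.8-fold and Gbp2b at least 8.77-fold lower. Against SU5402, Plk1 (3.67 ± 0.11), Nod1 (3.61), Olig1 (3.42) and Slc51a (3.17) were higher, with Ccl27a at least 5.98-fold and Gm13043 at least 5.71-fold higher. Dppa3 (-3.83 ± 0.06), Krt8 (-3.73 ± 0.07) and Fthl17f (-3.71) were lower, with Acta1 at least 16.1-fold, Gbp2b at least 11-fold and Gbp2 at least 8.16-fold lower. In all, 3880 probes were higher and 3914 lower than with chlorate (58.3%), and 3803 and 3947 than with SU5402 (57.9%). At least 2-fold, these counts were 392 and 554, and 397 and 536. With median scaling 60% of the calls against chlorate were higher, against 49.8%.

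Imprinted genes were lower in Ndst1/2-/- cells than with chlorate (12 of 13, median -1.25, or -1.04 with undetected genes at their bound) and than with SU5402 (11 of 13, median -1.29, or -1.08). Igf2 was lower by both (-3.41 ± 0.07 and -3.09 ± 0.07), and limma camera with Benjamini-Hochberg gave an adjusted p of 2.56e-06 and 7.88e-06 (adjusted p = 0.0253 and 0.0325 with an estimated correlation). ER stress genes were higher, 13 of 18 and 1 lower against chlorate (14 and 1 over the list alone; median 0.66) and 14 and 0 against SU5402 (median 0.51), among them Atf4 (1.52 ± 0.12 in both). Their adjusted p was 0.000114 and 0.000124 (limma camera with Benjamini-Hochberg; adjusted p = 0.0335 and 0.0344 with an estimated correlation). Trophectoderm genes were lower, 9 of 10 in both (medians -1.25 and -1.28, or -1.09 and -1 with undetected genes at their bound; limma camera with Benjamini-Hochberg, adjusted p = 5.58e-05 and 1.20e-05; adjusted p = 0.0464 and 0.0547 with an estimated correlation). Nodal targets were lower, 6 of 6 and 5 of 6 (6 over the list alone; medians -0.84 in both), with Lefty2 at -2.43 ± 0.07 and -2.59 ± 0.07 (limma camera with Benjamini-Hochberg, adjusted p = 0.00298 and 0.00505; adjusted p = 0.0459 and 0.0547 with an estimated correlation).

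Cell cycle genes were higher in Ndst1/2-/- cells, 14 of 20 and 2 lower against chlorate (15 and 3 over the list alone; median 0.34) and 11 and 3 against SU5402 (median 0.21; limma camera with Benjamini-Hochberg, adjusted p = 0.00421 and 0.0313; adjusted p = 0.0459 and 0.0809 with an estimated correlation). Of 15 p53 targets 11 were lower in both comparisons (12 over the list alone) and 2 and 1 higher, among them Cdkn1a (-1.60 ± 0.08 and -1.58 ± 0.08; limma camera with Benjamini-Hochberg, adjusted p = 0.00412 and 0.00293; adjusted p = 0.0567 and 0.0547 with an estimated correlation). LIF-STAT3 genes were higher, 7 and 6 of 11 with 1 lower in both, among them Bcl3 (1.07 ± 0.10 and 1.14 ± 0.10; limma camera with Benjamini-Hochberg, adjusted p = 0.0406 and 0.0261; adjusted p = 0.114 and 0.0809 with an estimated correlation). The LIF-STAT3 call against chlorate was lost without chlorate replicate 1 (0.0549), with the mean of all detected probes (0.0575) and in array set B alone (0.0535), and the call against SU5402 in array set B alone (0.0553). The cell cycle call against SU5402 was lost in array set A alone (0.0580).

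Of 9 BMP targets 7 were lower and 1 higher against chlorate (median -0.79, or -0.48 with undetected genes at their bound), among them Msx1 (-1.56 ± 0.08; limma camera with Benjamini-Hochberg, adjusted p = 0.0380; adjusted p = 0.211 with an estimated correlation). That call was lost with the authors' values (0.0528). Against SU5402 the osmotic stress genes (4 of 4 higher, median 0.54) and germline genes (5 of 7 lower and 1 higher, median -1.32, or -1.11 with undetected genes at their bound) were called (limma camera with Benjamini-Hochberg, adjusted p = 0.0261 each; adjusted p = 0.0809 with an estimated correlation). The germline list was not called against chlorate (limma camera with Benjamini-Hochberg, adjusted p = 0.0546), but passed without chlorate replicate 2 (0.0364), Ndst1/2-/- replicate 2 (0.0373) or 3 (0.0499), or SU5402 replicate 1 (0.0441). FGF-ERK genes were not called in either comparison (7 higher and 5 lower of 18 against chlorate, 2 and 9 against SU5402; limma camera with Benjamini-Hochberg, adjusted p = 0.618 and 0.283). The naive list (8 higher and 3 lower of 15, and 7 and 2) and the primed list (4 higher and 6 lower of 13 in both) were not called either (limma camera with Benjamini-Hochberg, adjusted p = 0.227, 0.115, 0.364 and 0.537).

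**Figure D4:**
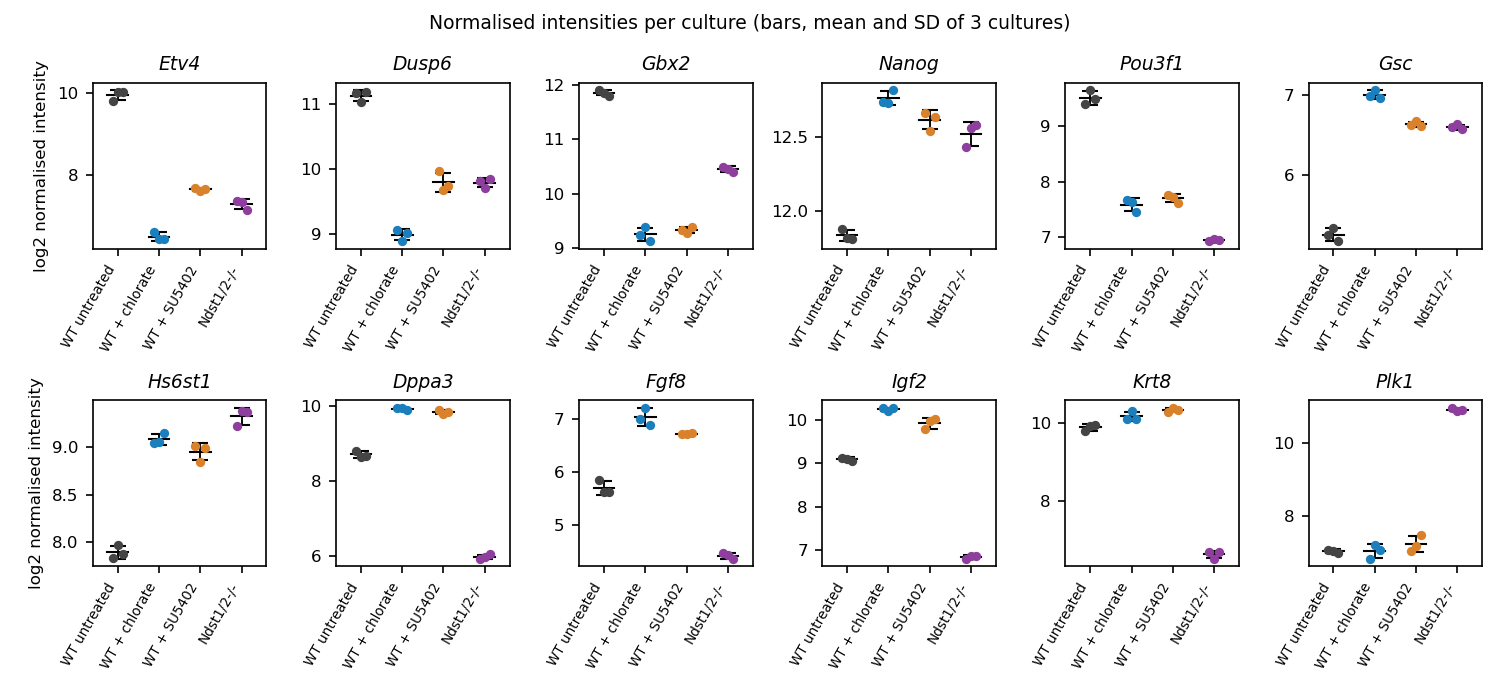
Log2 normalised intensity of 12 genes in each of the 12 cultures by group, with the mean and SD of 3 cultures. Each point is a culture.

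Chlorate and SU5402 changed many of the same genes in the same direction. Gata2, Spic, Lrrc15, Gsc and Sox21 rose and Etv4, Gbx2, Pou3f1, Spry4 and Myc fell with both, and 1258 probes were higher and 1153 lower with both, against 227 and 220 for independent lists of the same sizes. Only 8 probes were called in opposite directions, against 447. Across 13377 probes, which are not independent replicates, the log2 fold changes correlated at r = 0.875 (Spearman 0.795), and at 0.853 and 0.838 within array sets A and B. Both comparisons use the same untreated cultures, which alone gave r = 0.499 (at most 0.527) in 100 simulations without change. The covariance was 0.0690, against 0.00504 simulated, and 0.0626 to 0.0652 with a different untreated culture for each inhibitor. The 3 untreated cultures cannot be divided into sets of at least 2, so part of the overlap may come from shared controls.

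Ndst1/2-/- cells shared part of these changes. Of 2411 probes called in the same direction with both inhibitors, 69% were called in that direction in Ndst1/2-/- cells and 15.1% in the opposite direction. Over all 13377 probes, 4069 were called higher and 4312 lower in Ndst1/2-/- cells. All 3 comparisons had 843 probes higher and 820 lower, against 69.1 and 70.8 if all 3 lists were independent. The 2 inhibitor lists already share 1258 and 1153 probes, so 69.1 and 70.8 understate the overlap expected for Ndst1/2-/- cells. The overlaps with each inhibitor alone, given below, avoid this. Sox21 (2.91 in Ndst1/2-/- cells), Gsc and Hs6st1 were among the genes higher in all 3, and Etv4, Pou3f1, Wt1, Bmp4, Spry4 and Myc (-1.41, detected on 1 of 4 Ndst1/2-/- arrays) among those lower. Across probes the correlation with the Ndst1/2-/- comparison was 0.406 for chlorate (Spearman 0.398) and 0.409 for SU5402 (0.404). Those values lie under the 0.499 and 0.5 simulated for shared controls without change, where all groups spread equally. The median absolute change was 0.30 in Ndst1/2-/- cells, 0.14 with chlorate and 0.13 with SU5402. Their covariances of 0.0754 and 0.0663 exceeded the simulated 0.00505 and 0.00506, and the same-direction overlaps were 1169 higher and 1243 lower with chlorate (independent lists 579 and 612; opposite 630 against 1191) and 1028 and 1024 with SU5402 (486 and 499; opposite 502 against 986). Here too part of the overlap may come from shared controls.

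A group of 223 probes was higher with both inhibitors and lower in Ndst1/2-/- cells, and 141 were lower with both and higher in Ndst1/2-/- cells. Opposite calls were fewer than for independent lists with each inhibitor alone (630 against 1191 with chlorate, 502 against 986 with SU5402). Dppa3 (1.21, 1.12 and -2.71 with chlorate, with SU5402 and in Ndst1/2-/- cells), Igf2 (1.16, 0.83 and -2.26), Lefty1 (0.52, 0.61 and -1.23), Rhox6 (0.74, 1.05 and -1.03) and the endocytic adaptor gene Dab2 (0.60, 0.48 and -1.23) moved this way. Fgf8 did as well (1.33, 1.02 and at least 1.51-fold lower). Of the 8381 probes called in Ndst1/2-/- cells, 6718 (80.2%) were not called in the same direction with both inhibitors, and 4817 were called with neither. Only 2411 probes were called in 1 direction with both inhibitors, so most of the 8381 calls could not be shared.

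**Figure D5:**
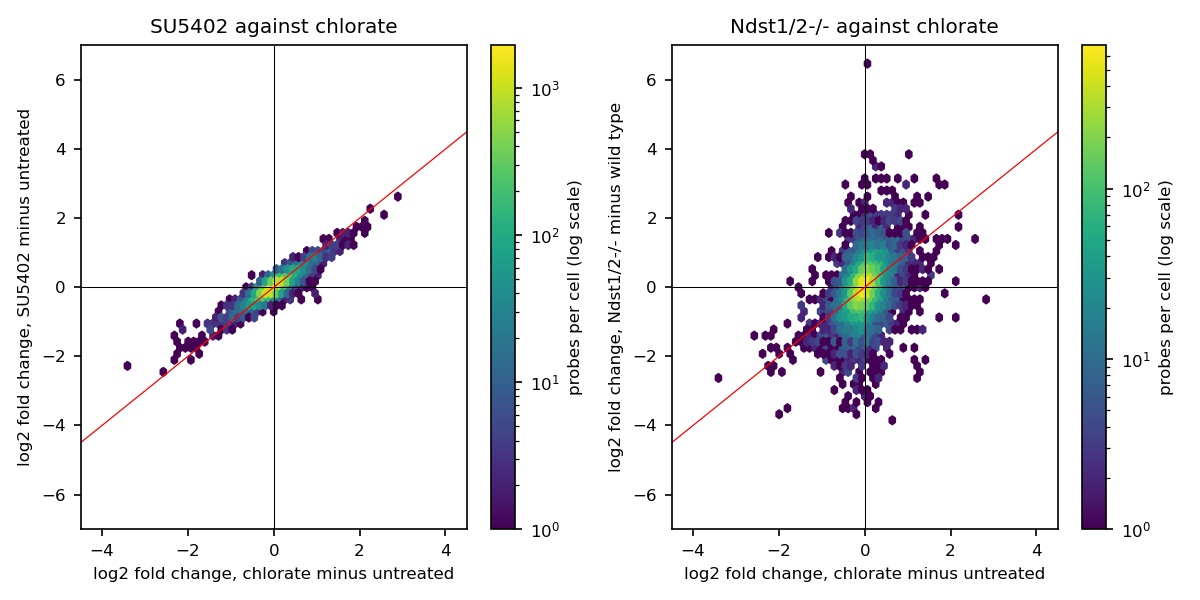
Log2 fold change per probe, SU5402 against chlorate and Ndst1/2-/- against chlorate, each compared with untreated wild-type cells. Shading is the number of probes on a log scale, and the red line marks equal change.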

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

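The alternatives by array set and by chromosome were chosen after results were seen, and the others before. Of 558 calls for named genes, 510 were kept with each culture left out in turn, and none reversed. In every alternative that tested the probe 298 were kept, and detection in all 12 cultures left some probes untested. The threshold of at least 2-fold alone ended 260 calls, which are all of those not kept in every alternative. Small changes can be missed: simulated changes of 0.25 log2 units were recovered in 22% of probes. Few probes were changed in that simulation, which makes the Benjamini-Hochberg cutoff strict. In the comparisons with untreated wild-type cells 23.5 to 62.7% of probes were called, so 22% does not describe the recovery there. Arrays detected 46.8 to 49.9% of probes, and genes with signal near background were not tested (5 of 14 mesendoderm genes on the array were). Except where a value shows it, the cause was not tested.

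A stricter threshold, an adjusted p under 0.01, gave 1248 probes higher and 1123 lower for chlorate, 955 and 824 for SU5402, and 30 and 43 for SU5402 against chlorate. Requiring a change of at least 2-fold left 94 and 77, 60 and 49, and 568 and 637 for chlorate, SU5402 and Ndst1/2-/- cells against untreated wild-type cells. It left 2 and 3 for SU5402 against chlorate, 392 and 554 for Ndst1/2-/- cells against chlorate, 397 and 536 against SU5402, and 1504 probes in the test of the 4 groups.

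With fewer arrays fewer probes were called. Array set A alone gave 1223 and 1037 for chlorate, 844 and 691 for SU5402, and 5 and 16 for SU5402 against chlorate. Array set B alone gave 1122 and 1024, 816 and 693, and 3 and 3. For SU5402 against chlorate, a model of only the 2 groups compared gave 39 and 80, the array set as a block 211 and 306, and median scaling 98 lower. Leaving out each culture in turn gave 64 to 146 probes higher and 88 to 210 lower in that comparison. The replicate block gave 1969 and 1970 probes for chlorate, 1699 and 1630 for SU5402, and 4127 and 4377 for Ndst1/2-/- cells, and it ended the list calls of primitive endoderm and cell cycle with SU5402 (limma camera with Benjamini-Hochberg, adjusted p = 0.0564 each) and of primed epiblast in Ndst1/2-/- cells (0.0686). It gained osmotic stress for SU5402 against chlorate (0.0387 against 0.0664). The labels do not say that replicate numbers mark a shared batch. Cultures of the same number correlated at -0.00942 to 0.190 (5 of 18 pairs over 0.1) and of other numbers at -0.174 to 0.118. Of 12 cultures 9 matched their own number best, a hint from the data and not from the design, and replicate 1 lies in array set A and replicate 2 in set B.

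The correlation of chlorate with SU5402 across probes was 0.851 without a filter, 0.853 in array set A, 0.838 in array set B, and 0.852 to 0.880 with each culture left out. With Ndst1/2-/- cells it was 0.412 and 0.397 for chlorate and 0.417 and 0.395 for SU5402 in sets A and B. Leaving out each culture gave 0.397 to 0.418 and 0.398 to 0.422.

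With an estimated correlation 0 lists were called for chlorate, 3 for SU5402, 1 for Ndst1/2-/- cells, 1 for SU5402 against chlorate, 5 for Ndst1/2-/- cells against chlorate and 2 against SU5402. The fry directional test, which makes no comparison with other genes, called 22, 15, 23, 13, 23 and 24 in that order. Array set B called 4 lists for SU5402, and array set A 4 for SU5402 against chlorate, where leaving out each culture gave 5 to 9. The osmotic stress list of Ndst1/2-/- cells was lost without chromosomes 8 and 11 (adjusted p = 0.0953, limma camera with Benjamini-Hochberg). Further list calls lost by array set were primitive endoderm (0.0824 in set B) and cell cycle (0.0958 in set A, 0.149 in set B) with SU5402, and primed epiblast in Ndst1/2-/- cells (0.0587 in set A, 0.0551 with the array set as a block). For SU5402 against chlorate they were FGF ligands and receptors (0.197, 0.0648 and 0.0571 with set A, set B and the block), trophectoderm (0.0847 and 0.0648 in sets A and B) and germline genes (0.0869 in set A). With the array set as a block cholesterol synthesis and osmotic stress passed for SU5402 against chlorate (0.0288 each), as did osmotic stress (0.0433) and germline genes (0.0368, and 0.0328 in set A alone) for Ndst1/2-/- cells against chlorate. List tests with this block took the 2 arrays of culture 3 as separate replicates, so lists gained only there may owe their call to that.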

Other observations

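The tests of explanations in this part were chosen after results were seen, and the regroupings of cultures before. Ndst1/2-/- cells had more called probes than either inhibitor, and a difference between the lines in copy number of chromosomes 8 and 11 could shift many genes (medians 0.32 and -0.33). Copy number was not measured, and the medians cannot tell which line would carry a gain or loss. Outside those chromosomes 7020 probes were still called (60.7% of 11567, which include probes with no assigned chromosome). A direct change in the dosage of genes of chromosomes 8 and 11 is thus not the whole cause. Whether such a change also altered genes of other chromosomes was not tested, so these calls cannot exclude it. Sequence differences under single probes are not the whole cause either: of 295 genes with several probes, 1 or more of them changed at least 2-fold, 92.5% moved in 1 direction on all probes. A difference between the cell lines other than the loss of Ndst1 and Ndst2 remains open. Of the calls 80.2% were not shared in direction with both inhibitors. That share is largely set by the counts, since 2411 probes were called in 1 direction with both inhibitors and 8381 in Ndst1/2-/- cells. With 1 line of each genotype the line and the genotype cannot be told apart.

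Chlorate and SU5402 moved many of the same probes. Deviations of single untreated cultures are not the whole cause. The lowest covariance with a different untreated culture for each inhibitor was 0.0626, against 0.00504 for simulated groups without change. A deviation common to all 3 untreated cultures would stay in both comparisons, so it cannot be excluded in this way. Induction of ER stress or the integrated stress response by both could also give overlap. Of 18 genes of that list 0 rose with either inhibitor, 8 fell with chlorate and 6 with SU5402, and the higher of the 2 medians was -0.128, which goes against induction. The downward list calls themselves were lost with an estimated correlation (limma camera with Benjamini-Hochberg, adjusted p = 0.0760 and 0.0921). The osmotic stress list (medians 0.03 and -0.02) and the oxidative stress list (-0.06 and 0.11) were not called with either inhibitor, and no other stress response was tested as an explanation.

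Lower primed and higher naive expression could come from fewer differentiated cells in the cultures. Markers of 5 other cell types (primitive endoderm, mesendoderm, neuroectoderm, trophectoderm and fibroblast, 41 genes) were called higher more often than lower with chlorate (16 against 4, Gata3 among them) and with SU5402 (21 against 4). The pooled markers thus gave no sign of fewer such cells. Neuroectoderm and fibroblast markers did not rise on balance with either inhibitor, so fewer cells of those types cannot be excluded. Some pooled markers were bright in untreated wild-type cells (mean log2 intensity 10.16 for Tfap2c and 10.89 for Sparc), so their rise need not come from other cell types. Sparc was chosen after its values were seen. In Ndst1/2-/- cells 10 were higher and 22 lower (median -0.26), with Krt8, Krt18 and Acta2 among the lower, so fewer differentiated cells there cannot be excluded.

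With 3 cultures per group a pair of groups allows 10 splits, too few to judge any result. The real split gave the most calls (1 of 10 each): 3803 probes for chlorate, 3145 for SU5402, 8381 for Ndst1/2-/- cells, 340 for SU5402 against chlorate, 7794 for Ndst1/2-/- cells against chlorate and 7750 against SU5402, with at most 0 in any other split. Lists called were 6, 8, 10, 8, 8 and 9 in the same order, against at most 3, 3, 7, 2, 6 and 4 in other splits. For the test of the 4 groups, 1 of 100 regroupings, the real one, reached 9229 probes, and the highest other gave 6363.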
